A study of Ictidomys tridecemlineatus with 31 samples.

How the data were processed

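Adrenal gland RNA of 30 squirrels in 6 hibernation states was sequenced as 31 libraries, prepared with 2 kits (Illumina TruSeq Stranded mRNA for 9 libraries, Nugen Universal Plus mRNA for 22). The submitters' processing notes name cutadapt, HISAT2, Salmon, DESeq2 and limma, without versions or roles. The genome build behind the gene models is not given in the sources used here, so no coordinates are printed. The deposited table held log2-scale values of 14015 genes, although its name calls them counts: they were continuous, ran from 4.51 to 21.01 and had library medians between 10.14 and 10.21. The transform that made them is not stated, and some such transforms compress differences at low levels. No read totals were kept, so the depth per library is unknown. The authors had removed a kit offset from every gene. The means of the TruSeq and Nugen libraries differed by at most 7.1e-15 on the log2 scale in any gene, so the offset was taken without regard to state. Names ending in _like or _containing were given by the file where a gene was named by sequence similarity or by an RNA it holds.

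Values were used as deposited and fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with lmFit and eBayes using the trend and robust settings. The model had a mean for each state and terms for kit and sex, with 22 residual degrees of freedom. On a log scale, a fit with the kit term gives the same state differences whatever kit offset was subtracted. The kit term was estimated from Ent, Ar and IBA, since LAr, SpD and SA had Nugen libraries alone. A test of kit by state interaction among those 3 states called 0 genes in limma, with 480 at an unadjusted p below 0.05. The 2 libraries of 1 Ent animal (replicates 3 and 5, 1 per kit) were averaged. Their residuals across genes correlated at 0.582, against 0.438 for the highest other pair of 465 pairs and a median of -0.02. Genes at or above a value of log2(10) in at least 5 animals were kept, which removed 0 genes. Tests were 2-sided with Benjamini-Hochberg adjustment over all genes per comparison and a threshold of 0.05. Levels are the deposited value minus the fitted kit term, on the scale of the Nugen libraries, with the SD over 5 animals.

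The comparisons, the test, the gene lists and the rule for named genes were chosen before the data were examined. The rule took, per comparison, up to 8 genes per direction with the largest change among those past the test that had a gene symbol, a mean level at or above the median gene, and no overlap between the animals of the 2 states. It added up to 5 members per described list and a fixed set of adrenal and stress genes. Genes described as named after their values were seen fall outside that rule. The lists covered early response, clock, heat shock, endoplasmic reticulum stress, cold-inducible, inflammatory, interferon, hypoxia, NRF2 and glucocorticoid response genes. They also covered steroid and cholesterol synthesis, the chromaffin cell, the zona glomerulosa, oxidative phosphorylation, fatty acid oxidation, ribosomal proteins, ribosome biogenesis, proteasome and cell cycle. Markers of endothelium, fibroblasts and capsule, macrophages, neutrophils, lymphocytes, erythroid cells, Schwann cells and glia, adipocytes, kidney and liver completed them. Of the list entries 539 matched a symbol exactly, 4 matched 1 of several entries, 23 matched a _like name and 141 were absent, among them every mitochondrially encoded gene. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, for lists with at least 5 members measured (3 for markers). Benjamini-Hochberg adjustment covered 27 lists in 8 comparisons, 216 tests. The same test with an estimated correlation is printed beside it.

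The method was tested on simulated data with the same design and model. Errors were drawn independently for each gene from a normal distribution with the real spread. Correlation between genes and outlying animals were not simulated, so the false calls below need not hold for the real data. Of genes shifted between LAr and Ar by 0.5, 1 and 2 on the log2 scale, 43 of 67, 62 of 67 and 65 of 66 were called, with 6 false calls among 176. The same simulation gave 13 false calls among 187 for IBA against LAr, above the 5% aimed at, and 1 call for Ent against IBA, where nothing was changed. The other 5 comparisons with nothing changed gave no calls. Alternatives left out the kit or the sex term, used libraries of 1 kit, entered the repeated animal otherwise, fitted only the 2 states compared, applied quantile normalization, changed the filter, the limma settings or the threshold, and omitted each library in turn. Pseudocounts did not apply to log2 values. No paired analysis was possible because the labels give no link between animals of different states and the replicate numbers only follow the order of the records.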

Results

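Gene expression in the adrenal gland was measured by RNA sequencing in the 13-lined ground squirrel (Ictidomys tridecemlineatus), a small rodent that hibernates by alternating days of torpor with brief returns to normal body temperature. The 31 libraries came from 30 animals in 6 states that the labels abbreviate as Ent, Ar, LAr, IBA, SpD and SA. The labels do not spell these out. In common usage of the field Ent stands for entrance into torpor, Ar for arousing, IBA for interbout arousal (the warm interval between torpor bouts), SpD for spring dark and SA for summer active. LAr is left as the labels write it. Tissue was collected by time and body temperature, per the labels' protocols. Each state had 5 animals, and 1 Ent animal was sequenced as 2 libraries that entered as their mean. The Ent, LAr, SpD and SA groups had 3 females and 2 males each, Ar had 2 females and 3 males, and IBA had 4 females and 1 male. LAr, SpD and SA were prepared with the Nugen kit alone, whereas Ent had 3 Nugen and 3 TruSeq libraries and Ar and IBA each had 2 Nugen and 3 TruSeq libraries. The table held log2 values of 14015 genes, between 4.51 and 21.01, with library medians between 10.14 and 10.21. The transform behind them is not stated, so a log2 difference need not equal a difference in RNA amount. Read totals are unknown from such values, so the depth behind each value cannot be stated. Below, a change is a log2 fold change ± its standard error from the limma fit with terms for state, kit and sex, and a level is a kit-adjusted log2 value as mean ± SD with n = 5 animals per state. The term adjusted p is limma's moderated test with Benjamini-Hochberg adjustment over all genes, or, for a whole list, camera's test adjusted over 216 list tests.

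**Figure D1:**
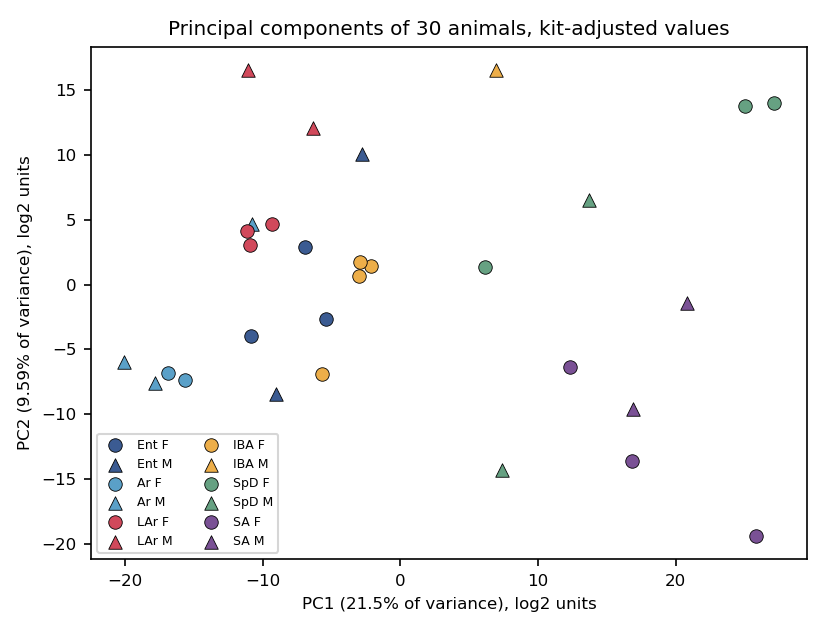
Principal components of the kit-adjusted log2 values of the 30 animals, with PC1 (21.5% of the variance) on the x axis and PC2 (9.59%) on the y axis, both in log2 units. Each point is 1 animal, coloured by state, with circles for females and triangles for males. The SpD and SA animals lie at positive PC1 (means 15.9 and 18.5), and Ent, Ar and LAr animals lie at negative PC1 (means -7, -16.3 and -9.8).

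Few annotated genes differed between Ent and Ar. Of 14015 genes, 13 were higher and 10 lower in Ar, and only 3 of the 23 carried a standard gene symbol. By the rule for named genes only Tesk2 (gene2107), which encodes a testis-associated protein kinase, was listed: it fell by 0.92 ± 0.14, from 12.27 ± 0.11 to 11.33 ± 0.27 (adjusted p = 0.00119). Cyr61 (gene16585), a matricellular protein gene of the immediate early class, rose by 0.95 ± 0.16 (adjusted p = 0.00412). The largest changes, named after their values were seen, were in poorly annotated loci. The locus named MIRLET7D_containing (G9278) fell by 2.27 ± 0.12, from 8.97 ± 0.30 to 6.67 ± 0.05 (adjusted p = 4.59e-12), and MIR656_containing (gene16446) fell by 1.02 ± 0.14 (adjusted p = 0.000195). The calcium-binding protein gene S100a4 (gene14095) fell by 0.84 ± 0.17 (adjusted p = 0.0206), a call lost in 6 of the 31 fits that omitted a library: Ent replicates 1, 4 and 6 and Ar replicates 3, 4 and 5.

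Among the 42 measured immediate early genes, the class of transcription factors and signalling regulators induced first after a stimulus, Cyr61 alone rose between Ent and Ar and 41 did not pass the test (2 rose when adjusted over the list alone). Fos stood at 9.34 ± 0.49 in Ent and 9.48 ± 0.30 in Ar, and Atf3 at 6.46 ± 0.19 and 6.53 ± 0.16. No gene of steroid hormone synthesis (19 measured), of the chromaffin cell (21), of heat shock (22) or of the clock (19) passed the test. The cytosolic ribosomal protein list tended lower in Ar, with a median of -0.12 and all 75 members negative but none past the test. Its list test gave adjusted p = 5.62e-13 with a preset correlation and adjusted p = 0.712 with an estimated correlation. The steroid synthesis list had a median of -0.15, or -0.06 under quantile normalization (adjusted p = 0.0096, and adjusted p = 0.197 with an estimated correlation). Markers of neutrophils, with 4 measured, had a median of -0.42 (adjusted p = 0.00327, and adjusted p = 0.31 with an estimated correlation). At an unadjusted p below 0.05 there were 811 genes. Within the Nugen libraries 7 genes passed, within the TruSeq libraries 9, and with only the 2 states compared in the fit 7.

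Between Ar and LAr, the immediate early genes rose together. Of the 42 measured members 28 rose and none fell, with a list median of 0.88, and 32 rose when adjusted over the list alone. The series title names this class as activated at arousal, so the direction of this list is not independent of the study. Atf3 (gene12452), a stress-induced transcription factor, rose by 2.99 ± 0.20, from 6.53 ± 0.16 to 9.50 ± 0.46 (adjusted p = 2.57e-10). Fos (gene5017), a subunit of the AP-1 transcription factor, rose by 2.75 ± 0.27 (adjusted p = 3.09e-07), and Btg2 (gene13276), an antiproliferative early response gene, rose by 2.76 ± 0.31 (adjusted p = 1.94e-06). Egr1 (gene10450) rose by 2.19 ± 0.28, Trib1 (gene494) by 1.98 ± 0.17, Junb (gene18630) by 1.78 ± 0.32, Dusp1 (gene16656) by 1.42 ± 0.23, Zfp36 (gene18838) by 1.41 ± 0.14 and Jun (gene9313) by 1.32 ± 0.19. The list test gave adjusted p = 1.05e-44, and adjusted p = 0.00453 with an estimated correlation. Rgs16 (gene3638), a regulator of G-protein signalling outside the list, rose by 1.48 ± 0.29 (adjusted p = 0.00301).

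**Figure D2:**
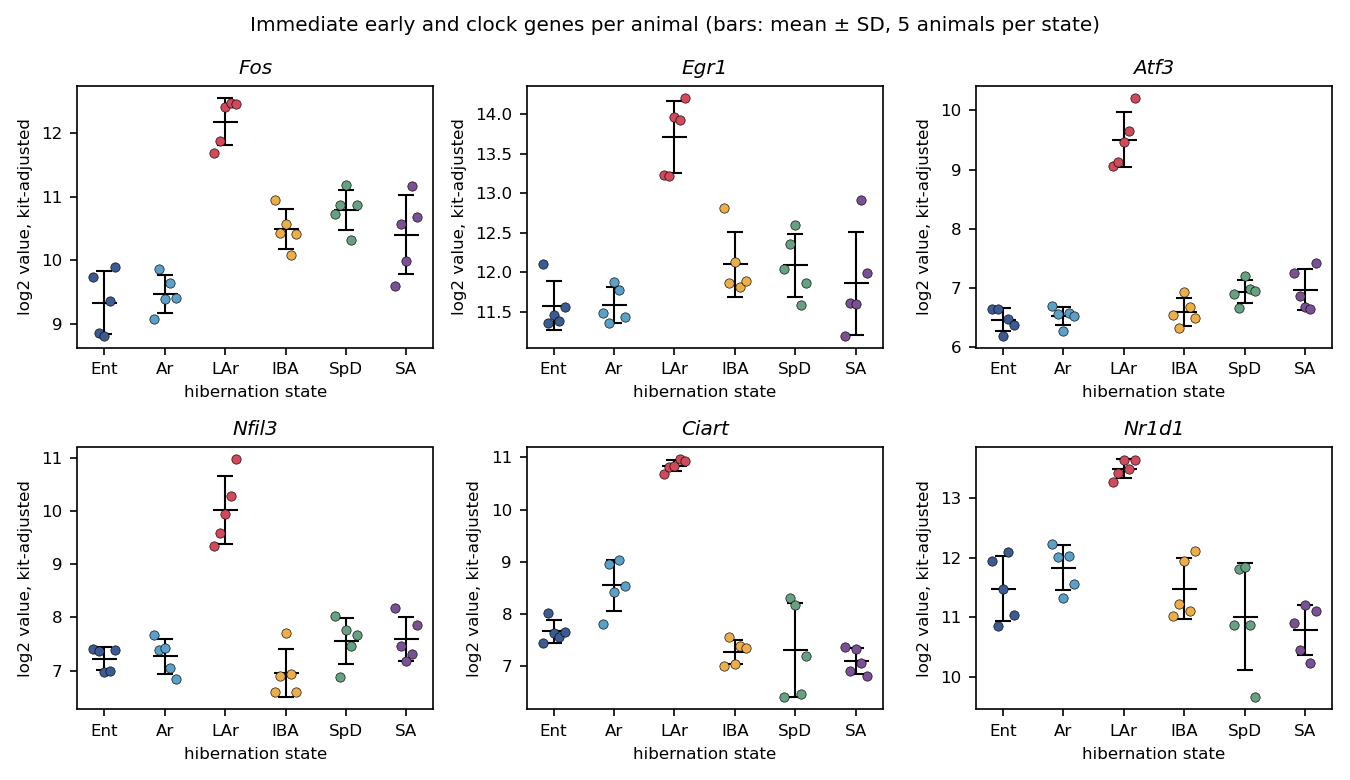
Kit-adjusted log2 values of 3 immediate early genes (Fos, Egr1, Atf3) and 3 genes of the clock list (Nfil3, Ciart, Nr1d1), with the hibernation state on the x axis. Each point is 1 animal, and the bars give the mean ± SD of 5 animals. In LAr, Atf3 stood at 9.50 ± 0.46 and Ciart at 10.84 ± 0.11, above every animal of the other 5 states.

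Between the same states, of 19 measured clock genes, 6 rose and none fell. Nfil3 (gene22874), a repressor of D-box-driven transcription, rose by 2.78 ± 0.30 (adjusted p = 1.26e-06). Ciart (gene14012), a repressor of CLOCK-BMAL1 activity, rose by 2.30 ± 0.32 (adjusted p = 3.64e-05). Bhlhe40 (gene13842) rose by 1.94 ± 0.29, Nr1d1 (gene5497), the REV-ERB alpha receptor gene, by 1.68 ± 0.37, and Bhlhe41 (gene11915) by 1.13 ± 0.24. Per1 (gene15500) rose by 0.89 ± 0.24 with adjusted p = 0.0442, and its call was lost in 17 of the 31 fits that omitted a library. The clock list gave adjusted p = 0.000327, and adjusted p = 0.351 with an estimated correlation. The labels give no collection time per sample, so time of day cannot be told apart from state for the clock genes, here and from LAr to IBA. Of 20 genes of endoplasmic reticulum stress, 7 rose and none fell. Ddit3 (gene18138), the CHOP transcription factor gene, rose by 1.21 ± 0.10 (adjusted p = 4.78e-09). The chaperone gene Hspa5 (gene4827), which encodes BiP, rose by 0.76 ± 0.10, from 14.51 ± 0.10 to 15.26 ± 0.14. Herpud1 (gene2246) rose by 0.68 ± 0.12 and Dnajb9 (gene18383) by 0.61 ± 0.08. That list gave adjusted p = 1.73e-11, and adjusted p = 0.0215 with an estimated correlation.

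Of 12 measured inflammatory response genes, 6 rose from Ar to LAr and none fell. Socs3 (gene15328), a suppressor of cytokine signalling, rose by 2.40 ± 0.29 (adjusted p = 5.3e-06). The NF-kappaB inhibitor genes Nfkbiz (gene17512) and Nfkbia (gene6246) rose by 1.74 ± 0.18 and 1.40 ± 0.10, and the chemokine gene CCL2 (gene10914) by 1.32 ± 0.23. In camera the list gave adjusted p = 7.32e-10, and adjusted p = 0.0733 with an estimated correlation. Of 16 glucocorticoid response genes 7 rose, among them Errfi1 (gene17234) by 1.67 ± 0.25 and Cebpd (gene15078) by 0.65 ± 0.14. That list gave adjusted p = 7e-09, and adjusted p = 0.0526 with an estimated correlation, and shares members such as Dusp1, Nfkbia and Per1 with other lists. Among the falls, Rhof (gene12598), a Rho family GTPase gene, fell by 0.80 ± 0.09 (adjusted p = 1.26e-06), Kiaa0907 (gene14175) fell by 0.75 ± 0.11 and Ahdc1 (gene1818) fell by 0.65 ± 0.12. The calcium release channel gene Ryr1 (gene22980) fell by 0.57 ± 0.14 (adjusted p = 0.0254), a call lost without LAr replicate 3 or 5 or Ar replicate 2 or 4.

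No steroid synthesis gene passed the test between Ar and LAr, with Star at 15.55 ± 0.13 in Ar and 15.47 ± 0.14 in LAr. All 21 chromaffin cell genes had lower estimates in LAr (list median -0.41) and none passed the test. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, had an estimate of -0.66 ± 0.23 (adjusted p = 0.142). That list gave adjusted p = 1.2e-06, and adjusted p = 0.582 with an estimated correlation. Of the 12 endothelial markers 1 fell, Robo4, at -0.51 ± 0.14 (adjusted p = 0.0342), a call lost in 9 of the 31 fits that omitted a library. The endothelial list median was -0.24 (adjusted p = 0.0105, and adjusted p = 0.707 with an estimated correlation). LAr replicate 4 lay apart, with a mean of these markers, centred over all animals, of -0.558. The other LAr animals lay between -0.131 and 0.026, and the Ar animals between -0.148 and 0.153. In all, 309 genes rose and 104 fell. Without LAr replicate 5 the count of 413 was 264, and within the Nugen libraries, with 2 Ar animals, it was 124.

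From LAr to IBA, 521 genes were higher and 402 lower in IBA. Of the 42 measured immediate early genes 24 fell and 2 rose (30 fell and 4 rose when adjusted over the list alone), with a median of -0.79. Atf3 fell by 2.90 ± 0.20 to 6.59 ± 0.23 (adjusted p = 8.84e-10), Fos fell by 1.63 ± 0.28 to 10.49 ± 0.31, Trib1 fell by 1.61 ± 0.17, Klf10 (gene591) fell by 1.57 ± 0.17, Junb fell by 1.57 ± 0.33 and Egr1 fell by 1.55 ± 0.29. The list gave adjusted p = 5.56e-21, and adjusted p = 0.0526 with an estimated correlation. Of the 19 clock genes 6 fell and none rose. Ciart fell by 3.56 ± 0.32, from 10.84 ± 0.11 to 7.27 ± 0.24 (adjusted p = 1.54e-07), Nfil3 fell by 3.06 ± 0.31, Nr1d1 fell by 1.98 ± 0.38, Bhlhe40 fell by 1.83 ± 0.30 and Per1 fell by 1.16 ± 0.25. The clock list gave adjusted p = 2.52e-05, and adjusted p = 0.197 with an estimated correlation.

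Of the 12 inflammatory genes 6 fell from LAr to IBA, with CCL2 at -1.33 ± 0.24, Nfkbiz at -1.12 ± 0.18 and Nfkbia at -0.70 ± 0.10. The list as a whole gave adjusted p = 0.00237, and adjusted p = 0.582 with an estimated correlation. Of the 20 endoplasmic reticulum stress genes 4 fell, among them Ddit3 at -0.77 ± 0.10 and Herpud1 at -0.60 ± 0.12, while the list median was -0.01 (0.03 under quantile normalization) and its test did not pass (adjusted p = 0.0716). Stbd1 (gene19739), a glycogen-binding protein gene, fell by 1.55 ± 0.26. The ribosomal RNA precursor RNA45SN5 (G29854) fell by 1.96 ± 0.53, from 13.77 ± 1.15 to 11.86 ± 0.34 (adjusted p = 0.0248). That call was lost without IBA replicate 1 or 2, LAr replicate 2 or 3, or Ent replicate 5. Both kits were made for mRNA, so these values need not follow the amount of the precursor. Among the rises, Rhof rose by 0.81 ± 0.09 (adjusted p = 1.54e-06), the methionine adenosyltransferase gene Mat2a (gene20900) by 0.70 ± 0.12 and the nonsense-mediated decay factor gene Smg5 (gene14192) by 0.67 ± 0.07. Zfc3h1 (gene13351) rose by 0.73 ± 0.13 and Kiaa0907 by 0.68 ± 0.11. Cirbp (gene14771), the cold-inducible RNA-binding protein gene, fell by 0.36 ± 0.09, from 14.38 ± 0.07 to 14.03 ± 0.07 (adjusted p = 0.0127), a call lost without IBA replicate 1. Rbm3, its cold-inducible relative, had an estimate of -0.38 ± 0.24 (adjusted p = 0.424). Of the 12 endothelial markers 2 rose, with Egfl7 (gene19313) at 0.37 ± 0.10, a call lost without LAr replicate 5 or IBA replicate 2, and 1 rose without IBA replicate 3. The 923 genes became 598 without IBA replicate 2 and 331 within the Nugen libraries, with 2 IBA animals. Leaving out the kit term gave 1440, and fitting only the 2 states compared gave 448. The latter fit took the kit term from IBA alone and so rested largely on the same 2 IBA animals.

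Between IBA and Ent, 425 genes were higher and 724 lower in Ent. Of the 42 immediate early genes 10 fell and 1 rose (16 and 2 when adjusted over the list alone). Cyr61 fell by 1.28 ± 0.16 (adjusted p = 4.58e-05), Btg2 fell by 1.27 ± 0.28, Fos fell by 1.21 ± 0.24, Dusp1 fell by 1.10 ± 0.21 and Srf (gene2674), the serum response factor gene, fell by 0.48 ± 0.08. Tested as a whole, the list gave adjusted p = 4.54e-07, and adjusted p = 0.478 with an estimated correlation. Of 22 heat shock chaperones 10 fell and none rose (15 fell when adjusted over the list alone). Hsph1 (gene1302) fell by 0.93 ± 0.19 (adjusted p = 0.00377), Hspa1a (gene21455) fell by 0.70 ± 0.16, Hspa4l (gene17952) fell by 0.52 ± 0.11 and Dnajb1 (gene18679) fell by 0.49 ± 0.11. Hspa1a and Hspa1b are near-identical copies, so reads of the pair are hard to assign to either. The heat shock list gave adjusted p = 1.07e-07, and adjusted p = 0.478 with an estimated correlation.

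Of 21 genes of the NRF2 oxidative stress response, 9 fell from IBA to Ent and none rose. They included Hmox1 (gene5947), the heme oxygenase 1 gene, at -0.85 ± 0.17 (adjusted p = 0.00247), the glutathione synthesis genes Gclm (gene10863) and Gclc (gene2557) at -0.76 ± 0.14 and -0.63 ± 0.14, and Srxn1 (gene4422) at -0.64 ± 0.13. In camera the list gave adjusted p = 8.33e-05, and adjusted p = 0.478 with an estimated correlation. Of 20 endoplasmic reticulum stress genes 4 fell, with Atf4 (gene5865) at -0.46 ± 0.09 and Hspa5 at -0.45 ± 0.10 (list adjusted p = 1e-05, and adjusted p = 0.197 with an estimated correlation). Of 31 proteasome genes 5 fell (list adjusted p = 0.000257, and adjusted p = 0.802 with an estimated correlation), and Psmd6 (gene17772) changed by -0.22 ± 0.06. Of 33 ribosome biogenesis genes 4 fell (list adjusted p = 0.000462, and adjusted p = 0.582 with an estimated correlation), and none passed under quantile normalization. The splicing kinase gene Clk1 (gene21358) fell by 0.84 ± 0.10 (adjusted p = 1.71e-05) and the transporter gene Abcc4 (gene1252) fell by 0.92 ± 0.22.

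From IBA to Ent, Smyd3 (gene9797), a lysine methyltransferase gene, rose by 1.05 ± 0.19 (adjusted p = 0.00121), the mitochondrial carrier gene Slc25a18 (gene23062) by 0.93 ± 0.23, Cd248 (gene16018) by 0.90 ± 0.18 and Dlg2 (gene6828) by 0.85 ± 0.15. Alas1 (gene10240), the first enzyme of heme synthesis, rose by 0.89 ± 0.24, a call lost without Ent replicate 1 or 6 or IBA replicate 1. Cirbp rose by 0.37 ± 0.08, from 14.03 ± 0.07 to 14.39 ± 0.04 (adjusted p = 0.00497). Of 19 steroid synthesis genes 1 rose, and none did under quantile normalization (median 0.26, or 0.16 under that normalization, list adjusted p = 0.0096, and adjusted p = 0.197 with an estimated correlation). The 12 fibroblast and capsule markers were all estimated higher in Ent (median 0.26), with none past the test (list adjusted p = 0.00404, and adjusted p = 0.582 with an estimated correlation). IBA replicate 3 held intestine-like transcripts far above their level in the other IBA libraries. Without it the count of 1149 was 788, the NRF2 count 6, the proteasome count 2 and the heat shock count 9, and no ribosome biogenesis gene passed. The count was 710 without Ent replicate 1, 735 without Ent replicate 6 and 418 with only the 2 states compared in the fit. It was 295 within the TruSeq libraries, where IBA replicate 3 was among 3 IBA animals. Within the Nugen libraries it was 0 (2 IBA animals, 1587 genes at an unadjusted limma p below 0.05).

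Steroid hormone synthesis genes were lower in IBA than in SA. Of 19 measured members 7 fell and none rose (8 fell when adjusted over the list alone), with a median of -0.40. Under quantile normalization 4 fell, with a median of -0.23. Star (gene20820), which moves cholesterol into mitochondria, fell by 1.43 ± 0.15, from 16.82 ± 0.27 in SA to 15.39 ± 0.20 in IBA (adjusted p = 9.82e-06). CYP11A1 (gene1046), the side-chain cleavage enzyme gene, fell by 1.48 ± 0.22 (adjusted p = 0.000482) and CYP17A1 (gene16155), which encodes the 17-hydroxylase, fell by 1.18 ± 0.19 (adjusted p = 0.000762). The lipoprotein receptor gene Scarb1 (gene12551) fell by 1.01 ± 0.27, a call lost without IBA replicate 1 or 2 or SA replicate 3, and the ACTH receptor gene Mc2r (gene17364) fell by 0.68 ± 0.19, a call lost without IBA replicate 2 or SA replicate 3. Nr5a1 (gene4815), the steroidogenic factor 1 gene, fell by 0.40 ± 0.12, a call lost in 8 of the 31 fits that omitted a library. The list gave adjusted p = 1.12e-06, and adjusted p = 0.00491 with an estimated correlation. CYP17A1 held the highest value of all genes in every one of the 31 libraries. Quantile normalization gives each rank the same value in every sample, so it set the CYP17A1 difference to 0. AKR1C1_like (gene4163), named by sequence similarity to an aldo-keto reductase family with close paralogs, fell by 1.40 ± 0.21.

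**Figure D3:**
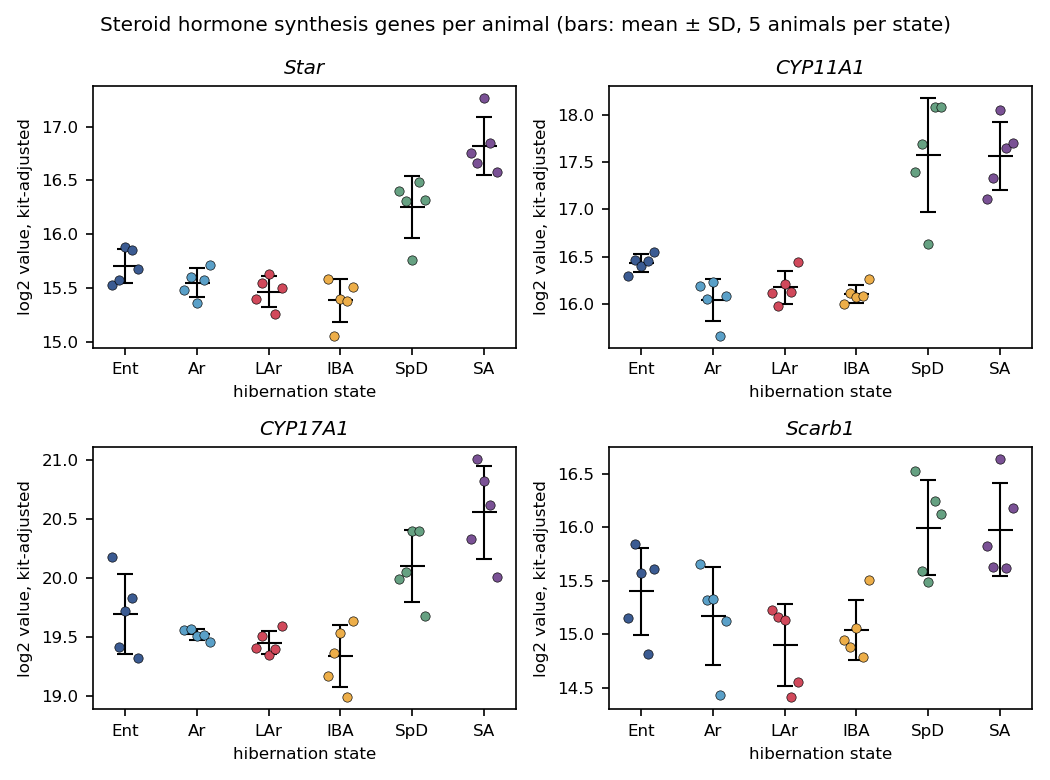
Kit-adjusted log2 values of Star, CYP11A1, CYP17A1 and Scarb1, with the hibernation state on the x axis. Each point is 1 animal, and the bars give the mean ± SD of 5 animals. Star stood at 16.82 ± 0.27 in SA, 16.25 ± 0.28 in SpD and 15.39 ± 0.20 in IBA.

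Between SA and IBA, of 58 nuclear-encoded oxidative phosphorylation genes 6 fell and none rose, among them the complex I genes Ndufs1 (gene17561) at -0.43 ± 0.09 and Ndufs2 (gene24483) at -0.36 ± 0.08 and the ATP synthase gene Atp5b (gene18114) at -0.30 ± 0.07. Under quantile normalization 3 fell. The list as a whole gave adjusted p = 4.13e-05, and adjusted p = 0.84 with an estimated correlation. Of 23 cholesterol synthesis and uptake genes 4 fell, among them Ebp (gene21083) at -0.53 ± 0.12 and CYP51A1_like (gene17176) at -0.63 ± 0.15 (lost without IBA replicate 2). Mvd (gene17887) rose, at 0.43 ± 0.11, a call lost without SA replicate 3. Without IBA replicate 3 the falls were 2. Tested as a whole, the list gave adjusted p = 0.0344, and adjusted p = 0.802 with an estimated correlation. Of 27 genes of fatty acid oxidation and PPARA targets, 4 rose and 3 fell, and the list test did not pass (adjusted p = 0.641). Without IBA replicate 3, 2 rose and 1 fell, and under quantile normalization 5 rose and 1 fell. Angptl4 (gene14988), an inhibitor of lipoprotein lipase, rose by 1.22 ± 0.20, from 11.78 ± 0.21 to 13.02 ± 0.20 (adjusted p = 0.00121), and Plin2 (gene18339), a lipid droplet coat gene, by 0.40 ± 0.11, a call lost in 5 of the 31 such fits. The mitochondrial reductase gene Decr1 (gene11662) fell by 0.50 ± 0.09. The metallothionein genes MT2A_like (gene2241) and MT1E_like (gene2240) rose by 1.04 ± 0.24 and 0.93 ± 0.19. They belong to a family of close paralogs, and in both IBA replicate 3 lay apart from the other 4 IBA animals.

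Of 12 endothelial markers 2 fell in IBA against SA, Flt1 (gene1285) at -0.67 ± 0.16 and Tek (gene16702) at -0.66 ± 0.17 (list median -0.27, adjusted p = 0.000453, and adjusted p = 0.582 with an estimated correlation). The fibroblast and capsule markers had a median of -0.26, with 1 of 12 past the test (list adjusted p = 0.024, and adjusted p = 0.678 with an estimated correlation). Of 4 neutrophil markers, Ltf (gene15572) at -0.81 ± 0.23 and Mmp9 at -1.71 ± 0.52 fell, calls lost in 4 and 17 of the 31 such fits. Of 21 chromaffin cell genes 1 rose and none fell, with Th at -0.43 ± 0.24 (adjusted p = 0.283) and Pnmt at -0.25 ± 0.26 (adjusted p = 0.618). Other large falls were Slc10a4 (gene3874) at -1.53 ± 0.34, Robo1 (gene7804) at -1.26 ± 0.27 and the tyrosine catabolism gene Hgd (gene10802) at -1.19 ± 0.21. In all, 518 genes were higher and 581 lower in IBA. The count of 1099 was 943 without IBA replicate 3, with 5 steroid synthesis genes falling, 553 without IBA replicate 2 and 522 without SA replicate 3. It was 658 without the kit term and 141 within the Nugen libraries, with 2 IBA animals. With only the 2 states compared in the fit it was 37. That fit took the kit term from IBA alone and so rested largely on the same 2 IBA animals.

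Between IBA and SpD, 5 of 19 steroid synthesis genes rose in SpD and none fell (7 rose when adjusted over the list alone), with a median of 0.31, and 3 rose under quantile normalization. CYP11A1 rose by 1.49 ± 0.22, from 16.11 ± 0.10 to 17.58 ± 0.60 (adjusted p = 0.00179), Star by 0.86 ± 0.15 (adjusted p = 0.00486) and Nr5a1 by 0.58 ± 0.12, a call lost without IBA replicate 1. CYP17A1 rose by 0.73 ± 0.19 and Scarb1 by 1.02 ± 0.27, calls lost in 4 and 5 of the 31 fits that omitted a library, IBA replicates 1 and 2 among them. Quantile normalization set the CYP17A1 difference to 0 here too. In camera the list gave adjusted p = 1.2e-06, and adjusted p = 0.00491 with an estimated correlation. Outside the list, the 5-alpha-reductase gene Srd5a1 (gene17646) rose by 0.95 ± 0.18 and AKR1C1_like by 1.14 ± 0.21. Slc25a18 rose by 1.58 ± 0.26 (adjusted p = 0.00316), and Xbp1 (gene18488), a transcription factor gene of the unfolded protein response, rose by 1.01 ± 0.15 (adjusted p = 0.00184). Alas1 rose by 1.10 ± 0.27, a call lost without IBA replicate 1 or 2 or SpD replicate 4. Arntl (gene10074), the BMAL1 gene, rose by 1.29 ± 0.35 with adjusted p = 0.0435, a call lost in 15 of the 31 such fits.

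Of 58 oxidative phosphorylation genes 6 rose in SpD and none fell, with 57 estimates above 0. Without SpD replicate 1, 17 rose, and under quantile normalization 2 rose. Ndufs2 changed by 0.49 ± 0.08 (list adjusted p = 3.11e-13, and adjusted p = 0.658 with an estimated correlation). Of 75 cytosolic ribosomal protein genes 3 rose (24 when adjusted over the list alone), with Rpl10 (gene23112) at 0.41 ± 0.09, a call lost without IBA replicate 1. Without SpD replicate 1, 19 rose, and without IBA replicate 3, 7 rose. Under quantile normalization none passed and the median was 0.07, against 0.22. That list gave adjusted p = 7.99e-17, and adjusted p = 0.658 with an estimated correlation. Angptl4 fell by 0.86 ± 0.20, a call lost without IBA replicate 2 or SpD replicate 4, and Decr1 rose by 0.49 ± 0.09. The NRF2 genes Srxn1 and Nqo1 (gene2419) fell, at -0.64 ± 0.15 and -0.60 ± 0.14. The Srxn1 call was lost without IBA replicate 1 or SpD replicate 5, and the Nqo1 call without IBA replicate 1 or 2. The transcription factor gene Znf366 (gene12006) fell by 0.64 ± 0.12 and the phosphodiesterase gene Pde5a (gene23872) fell by 0.59 ± 0.13. All 10 adipocyte markers were estimated higher in SpD (median 0.67), with none past the test over all genes and 5 adjusted over the list alone (list adjusted p = 0.000604, and adjusted p = 0.582 with an estimated correlation). Of 12 fibroblast and capsule markers 2 rose (1 under quantile normalization), among them Col1a1 at 0.70 ± 0.19, a call lost in 9 of the 31 such fits. In all, 300 genes were higher and 179 lower in SpD, and under quantile normalization the split was 246 and 227. The 479 genes became 122 without IBA replicate 1, 194 without IBA replicate 2, 161 without SpD replicate 4, 271 without SpD replicate 5 and 1020 without SpD replicate 1. They were 64 without the kit term and 17 within the Nugen libraries, with 2 IBA animals. With only the 2 states compared in the fit they were 0 (1858 at an unadjusted limma p below 0.05). That fit took the kit term from IBA alone and so rested largely on the same 2 IBA animals. Of 100 splits of these animals into groups of the same sizes, 5 reached the count, the real one included.

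From SpD to SA, both prepared with the Nugen kit alone, 11 genes were higher and 8 lower in SA, and 1828 had an unadjusted limma p below 0.05. The rises included Nuggc (gene19698), a nuclear GTPase gene, at 0.76 ± 0.13 (adjusted p = 0.00784), the septin gene Sept6 (gene3320) at 0.52 ± 0.08 (adjusted p = 0.00432) and Nell1 (gene18401) at 0.77 ± 0.15 (adjusted p = 0.0376, a call lost in 7 of the 31 fits that omitted a library). Gla (gene23153), the alpha-galactosidase A gene, rose by 0.50 ± 0.10 (adjusted p = 0.0494) and the NAD kinase gene Nadk2 (gene8976) by 0.30 ± 0.06 (adjusted p = 0.0376), calls lost in 25 and 14 of the 31 such fits. Cmbl (gene17966) fell by 0.62 ± 0.13 (adjusted p = 0.0376), a call lost in 14 of them. Rad9a (gene15981), a checkpoint gene, fell by 0.44 ± 0.08 (adjusted p = 0.0247), a call lost without SA replicate 2, 3 or 5 or SpD replicate 4. Among genes named after their values were seen, FCN1_like (gene19343) fell by 1.54 ± 0.17 (adjusted p = 1.64e-05), the glycerol channel gene Aqp7 (gene9486) fell by 0.89 ± 0.13 (adjusted p = 0.00178), and Inf2 (gene17145) rose by 1.07 ± 0.19. No steroid synthesis gene passed the test. Star had an estimate of 0.57 ± 0.13 (adjusted p = 0.0789) and CYP11A1 of -0.01 ± 0.19. Of the 75 ribosomal protein genes none passed over all genes and 54 fell when adjusted over the list alone, with a median of -0.22 (list adjusted p = 3.94e-29, and adjusted p = 0.478 with an estimated correlation). The adipocyte markers had a median of -0.67 in SA against SpD (list adjusted p = 0.000453, and adjusted p = 0.582 with an estimated correlation) and the kidney markers a median of 0.44 (list adjusted p = 0.00444, and adjusted p = 0.326 with an estimated correlation). The 19 genes became 257 without SpD replicate 1, 33 without SA replicate 1, 9 without SA replicate 3 and 10 without SA replicate 5. They were 11 without LAr replicate 1, IBA replicate 5 or SpD replicate 4 in turn, and 12 without LAr replicate 3. With only the 2 states compared in the fit 1 gene passed, and 9 of 100 splits of these animals reached the count, the real one included.

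**Figure D4:**
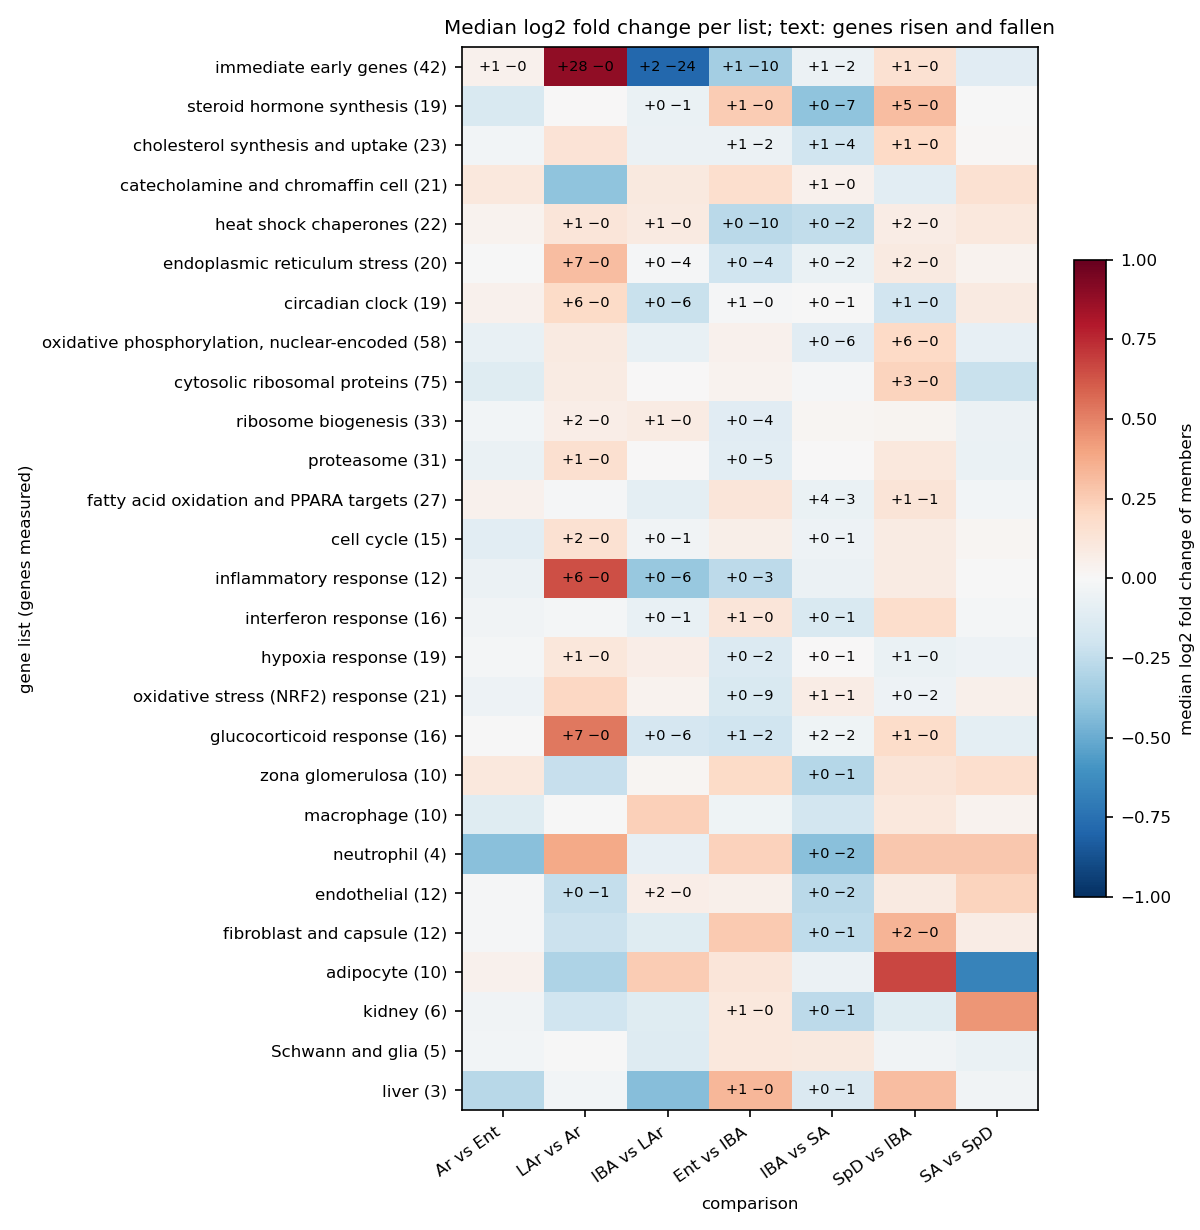
Median log2 fold change of the members of each fixed gene list (rows, with the number of genes measured) in the 7 comparisons of states (columns), on a colour scale from -1 to 1. Text in a cell gives the number of members that rose and fell at adjusted p below 0.05 over all genes. The immediate early genes stand at 0.88 in LAr against Ar, with 28 members risen, and at -0.79 in IBA against LAr, with 24 members fallen.

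Sex differences were few. Over all states 7 genes were higher and 2 lower in females. The locus XIST_containing (gene19958), which holds the RNA of the inactive X chromosome, was higher by 5.82 ± 0.45 (adjusted p = 2.22e-08). Among genes with escape from X inactivation, Kdm6a (gene7488) was higher by 0.51 ± 0.06 (adjusted p = 1.58e-05), Ddx3x (gene7469) by 0.38 ± 0.06 and Kdm5c (gene22208) by 0.27 ± 0.04. Sema3c (gene23134) was higher by 0.33 ± 0.05 and Grhpr (gene9572) was lower, at -0.23 ± 0.04. Star and CYP17A1 showed no difference that passed the test, at -0.02 ± 0.08 and -0.16 ± 0.10. The library labelled Ent replicate 4 is labelled female and held XIST_containing at 7.48, whereas the other 17 female libraries lay between 13.61 and 14.78 and the 13 male libraries between 7.05 and 9.18. Without that library the count of 9 was 18.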

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

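In this part the tests of the Ent replicate 4 library, of intestinal, smooth muscle and kidney markers in IBA replicate 3, and of kits and cell type shares behind the immediate early genes were chosen after the results were seen.

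The library labelled Ent replicate 4 is labelled female and held XIST_containing at 7.48, in the range of the male libraries. Mean position of 4 X-linked genes between the male mean (0) and the mean of the other females (1) was 0.334. It was 0.491 to 1.377 in the other females and -0.522 to 0.288 in males. These 4 genes were called between the sexes in a fit that counted this library as female, so their choice favoured a female position. A wrong sex label or an exchanged sample stays open, as does loss of XIST expression in a female. An exchange of sex labels with a male library of the series was argued against, since 0 libraries labelled male held XIST_containing in the female range.

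IBA replicate 3 had intestine-like transcripts far above their level in the other IBA libraries, such as Lgals4 at 13.75 against 7.49 ± 0.53 and Anpep at 14.56 against 9.02 ± 0.30 (mean ± SD of 4 animals). Of 40 intestinal markers not used to notice this, 5 were measured, with a median excess of 1.242 and 3 at their highest of the 30 animals, so intestinal tissue in the sample may be the source. The most abundant of them, Epcam, stood at 13.19 against 11.94, and all 5 were also measured in the other adrenal libraries. Of 14 smooth muscle markers 9 were measured, with a median excess of 0.637 and 2 at their highest of the 30 animals. Of 14 kidney markers 6 were measured. Kidney tissue was argued against by their median excess of -0.259, with 0 at their highest of the 30 animals, although Calb1 had an excess of 1.212. A mislabelled sample of another tissue was argued against by a median difference of 0.018 in 19 steroid synthesis genes. Among these the largest excess was 3.038, in AKR1C3_like. IBA replicate 3 is the only male of its state, and a biological explanation was not tested.

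The immediate early genes were higher in LAr than in Ar, with a median of 1.302 for the 28 that rose. The kits were argued against by a median of 1.282 within the Nugen libraries, with 2 Ar animals, where 19 of the 28 passed the test. All 28 were positive there. They were chosen in a fit that held the same libraries, so their sign and the size of that median were partly set in advance. A change in the share of a cell type with a marker list was argued against by a highest marker median of 0.379 (neutrophils, of 9 lists). That median covers all members of its list, and over all measured immediate early genes the median was 0.88. Handling or time of day at collection cannot be told apart from state, since the labels give 0 collection times per sample. A response to arousal itself may account for the rise and remains a hypothesis.

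Other splits of the animals into groups of the same sizes, 100 per comparison with the real one included, were counted. Chance was argued against for Ar against Ent (real count 23, highest other 4), LAr against Ar (413 and 2), IBA against LAr (923 and 0), Ent against IBA (1149 and 131) and IBA against SA (1099 and 31), where 1 split, the real one, reached the count. The split behind the 131 genes grouped Ent replicates 1, 2 and 4 with IBA replicates 1 and 2. Of these only Ent replicate 1 was a TruSeq library. The other group held Ent replicate 6 and IBA replicates 3, 4 and 5, all TruSeq, and the animal sequenced with both kits. That split thus largely followed the kit. For F against M, with sex labels permuted within states, 2 of 100 labellings reached the 9 genes, the real one included. Another labelling gave 11, so chance was made less likely but was not excluded. The real labelling kept the doubted female label of the library labelled Ent replicate 4. For SpD against IBA 5 of 100 reached 479 (highest other 1133, which grouped IBA replicates 1, 2 and 3 with SpD replicates 1 and 3), so chance was not excluded. For SA against SpD 9 of 100 reached 19 (highest other 272, which grouped SpD replicate 1 with SA replicates 1, 2, 3 and 5), so chance was not excluded there either. That split kept 4 of the 5 animals of each state together, and without SpD replicate 1 the real comparison gave 257 genes. SpD replicate 1 lay at -14.3 on PC2, whereas the other SpD animals lay between 1.35 and 14.1 and the SA animals between -19.4 and -1.45, so its place may have lowered the count of 19. The split with 1133 genes was the highest of those drawn. On PC1 its SpD replicates 1 and 3 lay at 7.4 and 6.1, next to the IBA animals at -5.69 to 6.93. SpD replicates 2, 4 and 5 lay further off, at 13.7, 25 and 27.2. The split may reflect this spread within SpD or another structure of the SpD and IBA samples, which was not tested.

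Sex and state interacted in 10 genes between SA and SpD (1752 at an unadjusted p below 0.05). SpD had 2 males, SpD replicate 1 among them, which lay apart from the other SpD animals on PC2. The interaction was not tested without that animal. In limma 0 genes did so between Ar and Ent (350 unadjusted) and 0 between LAr and Ar (395 unadjusted). The comparisons with IBA were not tested for it, since IBA had 1 male.

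Single animals lay apart from the other 4 of their state in 28 of 388 gene-by-state groups by Dixon's ratio of gap to range. Chance gives about 1 in 20 groups. IBA replicate 3 accounted for 7: Trib1 (ratio 0.755), Kiaa0907 (0.791), Irf1 (0.756), CYB5B_like (0.724), Plin2 (0.774), MT2A_like (0.747) and MT1E_like (0.732). In that animal MT2A_like stood at 12.32 against 10.98 ± 0.18 and Plin2 at 13.93 against 14.29 ± 0.05. The other IBA animals were replicate 1 for Robo1 (0.719) and Egfl7 (0.726), replicate 2 for Txnip (0.781), and replicate 4 for Atp5b (0.753) and Srd5a1 (0.837). In Ent they were replicate 1 for Egr1 (0.723), Dnajb1 (0.759) and Abcc4 (0.817), replicate 4 for Dusp1 (0.747) and Nfkbia (0.884), and replicate 6 for Socs3 (0.77). In LAr they were replicate 1 for Arntl (0.839), at 8.72 against 10.13 ± 0.14, replicate 3 for Klf10 (0.721) and replicate 4 for Robo4 (0.782). In SpD they were replicate 3 for Star (0.753), at 15.76 against 16.38 ± 0.08, and replicate 4 for Ndufs2 (0.769), Pdzd4 (0.71) and Rad9a (0.724). In SA they were replicate 1 for Fam151a (0.739), replicate 2 for CYB5B_like (0.859) and replicate 3 for Mc2r (0.717).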

How the results depend on the processing

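The TruSeq libraries alone and the list counts without IBA replicate 3 were chosen after the values were seen. Within the Nugen libraries the counts were 7 for Ar against Ent, 124 for LAr against Ar, 331 for IBA against LAr, 0 for Ent against IBA (1587 at an unadjusted limma p below 0.05), 141 for IBA against SA, 17 for SpD against IBA, 10 for SA against SpD and 3 for F against M. Within the TruSeq libraries they were 9 for Ar against Ent and 295 for Ent against IBA, where IBA replicate 3 was among 3 IBA animals. With only the 2 states compared in the fit the counts were 7 (Ar against Ent), 448 (IBA against LAr), 418 (Ent against IBA) and 37 (IBA against SA). They were 0 for SpD against IBA (1858 at an unadjusted limma p below 0.05) and 1 for SA against SpD. Between IBA and LAr, SA or SpD, such a fit took the kit term from IBA alone. Those comparisons thus rested largely on the 2 IBA animals with Nugen libraries. Without the kit term the counts were 1440 for IBA against LAr, 658 for IBA against SA and 64 for SpD against IBA. All TruSeq libraries came from Ent, Ar and IBA. The offset removed without regard to state thus also held part of their difference from LAr, SpD and SA. A fit without the kit term does not restore that part, so its comparisons between those groups of states are biased. At an adjusted p threshold of 0.01 the counts were 204 for LAr against Ar, 427, 387, 293, 83 and 9 for the next 5 comparisons in the order of the report. With both libraries of the repeated animal as separate replicates F against M gave 14. Omitting each library in turn gave 16 to 25 genes for Ar against Ent, 264 to 475 for LAr against Ar, 598 to 1059 for IBA against LAr, 710 to 1269 for Ent against IBA, 522 to 1256 for IBA against SA, 122 to 1020 for SpD against IBA, 9 to 257 for SA against SpD and 6 to 18 for F against M. Quantile normalization set the log2 fold change of CYP17A1 to 0 in IBA against SA and in SpD against IBA. Of the 216 gene list tests 71 passed with the preset correlation and 4 with an estimated one. Of 206 results for named genes that passed, 140 passed in every fit that omitted a library, 158 without the kit term and 74 within the Nugen libraries. With only the 2 states compared in the fit, which gives no result for sex, 98 passed and 100 did not. Dropping the filter changed nothing, and the stricter filter left 14013 genes.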

Other observations

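The genes of this part were chosen after their values were seen, apart from the fixed lists. Txnip (gene23861), a glucose-responsive inhibitor of thioredoxin, fell by 0.98 ± 0.17 from LAr to IBA (adjusted p = 0.000634), from 16.20 ± 0.12 to 15.21 ± 0.15. Ccnd2 (gene16528), the cyclin D2 gene, fell by 1.04 ± 0.19 in IBA against SA, from 12.09 ± 0.28 to 11.04 ± 0.24 (adjusted p = 0.00224). The iron carrier gene Tf (gene10281) fell by 1.16 ± 0.21 in the same comparison (adjusted p = 0.00243). Podxl (gene13951), a sialomucin gene, fell there by 0.68 ± 0.17 (adjusted p = 0.0171), a call lost without IBA replicate 2. Wdr72 (gene849) was higher in SA than in SpD by 0.88 ± 0.12 (adjusted p = 0.00134), and Abcc9 (gene11939), a potassium channel subunit gene, by 0.72 ± 0.11 (adjusted p = 0.00178). Aurka (gene23953) and Pcna (gene4334), genes of cell division, rose from Ar to LAr by 0.48 ± 0.09 and 0.29 ± 0.08, the 2 of 15 cell cycle genes that did. That list gave adjusted p = 0.0122, and adjusted p = 0.678 with an estimated correlation.

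Other fixed lists gave the following. Of 16 interferon response genes 1 rose from IBA to Ent (median 0.12, list adjusted p = 0.0621). Of 19 hypoxia response genes 2 fell from IBA to Ent, Pfkfb3 (gene4146) at -0.48 ± 0.12 and P4ha1 (gene9211) at -0.40 ± 0.12 (list adjusted p = 0.0084, and adjusted p = 0.197 with an estimated correlation). Of 10 zona glomerulosa genes 1 fell in IBA against SA (median -0.28, or -0.15 under quantile normalization, list adjusted p = 0.0547). No macrophage marker (10 measured) passed the test between Ent and Ar, where the list gave adjusted p = 0.0143, and adjusted p = 0.707 with an estimated correlation. The 5 Schwann cell and glia markers had a median of -0.07 in SA against SpD (list adjusted p = 0.74). Of 3 liver markers 1 rose from IBA to Ent (list adjusted p = 0.228). The 2 lymphocyte markers, the 1 erythroid marker and the 2 cold-inducible genes were too few for a list test, with medians of -0.43, -0.78 and 0.33 in IBA against SA, where 1 lymphocyte marker fell.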
